A study of Mus musculus with 2 samples.

How the data were processed

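H3K4me3 ChIP-seq libraries of embryonic facial prominence at embryonic day 13.5 were deposited for 2 biological replicates of mouse strain B6NCrl, with males and females pooled and a fragment size range of 300 to 500 bp per the labels. The authors deposited 4 peak lists on genome build mm10: 1 per replicate, 1 called on both replicates together (pooled) and 1 of replicated peaks, which per the deposited README text were derived from the pooled list and the replicate lists. Control alignments are listed there among the inputs of the peak lists. The aligner, the peak caller and their versions are not given in the sources used here, and reads and signal tracks were not analysed here. In the deposited lists the signal value of each peak is a ratio, taken as the fold over control on a linear scale. That reading is inferred from the values, which are all above 1 and rise with the significance column (Spearman's rho 0.995 to 0.997). The significance of each peak is the −log10 of its q value in the deposited lists, whose lowest value was 0.215 in replicate 1, 0.226 in replicate 2, 0.275 in the pooled and 0.485 in the replicated list. Fold per peak is thus the authors' value, and shares, widths, overlaps and tests were computed here. Read depth per library is not given, so no counting error could be attached to a fold. The spread between the replicates is the only measure of error, and it belongs to the replicate values. Folds of the replicated list are those of the pooled calls and can lie above both replicates, with 74.2 at Ssbp3 against 66.5 and 66.6. At other genes, such as Sftpc, they lie between them.

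Every kept peak was found in the pooled list with equal values. The rule by which 1777 kept peaks without a 50% overlap in both replicates entered the replicated list is not given in the sources used here, and a stricter list without them was run as an alternative. Peaks were compared with bedtools 2.31.1, requiring 50% of a peak's length to be covered, and against 100 seeded shuffles within chromosomes that excluded runs of at least 100 undetermined bases. Genes were taken from GENCODE M21 (Ensembl 96) on GRCm38.p6, the build of the lists, on which no peak passed a chromosome end. A gene was called marked when a peak overlapped the 1 kb on either side of any of its annotated TSSs. Peaks within 1 kb of each other were merged into domains, the widest domain at a TSS was assigned to the gene, and the widest 5% of coding TSS domains were called broad. Fold of a gene is the highest among its TSS peaks, which can lie outside its widest domain where a gene has several TSSs and holds for that peak, not for the whole of a merged domain. Distal peaks lay over 5 kb from any TSS. CpG-rich promoters had a CpG observed over expected above 0.6 and GC above 50% in the 1 kb on either side of the TSS at the gene's 5′ end. Software was python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and pysam 0.24.0, and samtools 1.23.1.

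The 17 gene lists, the tests, the thresholds, the first set of alternatives and the rule for named genes were fixed before the data were examined. The lists hold 432 entries and 416 distinct genes: facial mesenchyme transcription factors, facial signalling, orofacial cleft, cartilage and bone, epithelium, skeletal muscle, endothelium, erythroid cells, macrophages and leukocytes, neurons and glia, forebrain with eye and olfactory placode, liver and gut, heart, kidney and lung, pluripotent and germ cells, housekeeping and Hox. The kidney and lung list, also called kidney below, holds genes of gonad and thyroid as well. Ahsp was not found in the annotation. Another list also holds 5 of the 36 facial transcription factors, 4 of the 31 signalling, 16 of the 34 cleft, 3 of the 28 cartilage and bone and 4 of the 27 epithelial genes. Each list was compared with all other coding genes by a two-sided Fisher's exact test, for marking among all coding genes and for broad domains among marked ones, with Benjamini-Hochberg adjustment over the 17 lists and a threshold of 0.05. Genes next to each other can share a peak and a domain, which these tests do not take into account. Median widths were set beside 10000 random lists of marked genes of the same size, and the same comparison for fold was chosen after the data were seen. Hox paralog groups 1 to 4 and 9 to 13 were compared by a two-sided Fisher's exact test. The shares of peaks per genomic class were compared with the shuffles by a one-sided permutation p in the direction observed, and no other p is given across peaks.

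Genes named in the text are, by the fixed rule, the 10 coding genes with the widest TSS domains, the 10 with the highest fold, up to 3 marked members with the widest domains and up to 3 unmarked members in alphabetical order from each list, all marked Hox genes, the 5 distal peaks of highest fold, the 5 widest distal domains, and the 5 strongest peaks of each replicate untouched by the other. Any other gene is named as chosen after its values were seen.

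Alternatives changed 1 choice at a time: an overlap of 1 bp or of 80% both ways, the strongest 20000 peaks of each replicate, peaks with a −log10 q of at least 5, TSS windows of 500 bp and 2.5 kb, the 5′ end TSS alone, the pooled list, either replicate left out, CpG-rich promoters alone, merging of touching peaks only or within 3 kb, the widest 10% as broad, and distal distances of 2.5 and 10 kb. Added after the data were seen were the strict list, genes with no other coding TSS within 2 kb, genes with no other coding TSS in the domain, and promoters that are not CpG-rich. The pipeline was tested on simulated data: 4 of 4 overlap settings equalled bedtools, all 200 seeded broad genes were recovered (100%), 0.0646% of isolated unmarked genes were called marked, and of 200 random lists 4% had p under 0.05 and 0 after adjustment. The seeded domains were 12000 bp wide at isolated genes and all other simulated peaks were far narrower. Their recovery was thus fixed by the setting and checks the code alone. Genes of the random lists were drawn at random, so their rate does not cover lists whose members share peaks. With 1 group of 2 replicates, no test between conditions was possible.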

Results

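The measurement was ChIP-seq of H3K4me3, a histone modification of active and poised promoters, in the facial prominences of mouse embryos at embryonic day 13.5, the tissue from which the jaws, palate and nose form. The embryos were of strain B6NCrl with both sexes pooled, and the samples formed 1 group of 2 biological replicates. The labels give no treatment, second tissue or second stage, so each comparison below is between gene groups or regions within this tissue. The tests count genes or peaks of a single list, and the replicate lists show how far each value varied. Replicate 1 had 29299 peaks (39.0 Mb, median fold over control 12.5) and replicate 2 had 31108 (40.2 Mb, median fold 10.1). The list called on both replicates together held 32749 peaks (44.3 Mb), and the replicated list, the part of it kept by comparison with the replicates, held 25277 (42.3 Mb). Those 25277 peaks had a median width of 1428 bp, a largest width of 16546 bp and folds from 1.34 to 75.6. Read depth is unknown, since the files give no counts per library. Folds and widths from the replicated list have no replicate error of their own, and the mean ± SD beside them comes from the separate replicate lists.

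The replicates shared most peaks and nearly all strong ones. Of the peaks of replicate 1, 82.3% were covered over at least 50% of their length by peaks of replicate 2, and the share the other way was 77.0%. After shuffling replicate 2 within chromosomes the share was 1.497%, with 1.70% the highest of 100 shuffles. The Jaccard index in base pairs was 0.825. Across 20919 peaks that overlapped a single peak of the other replicate, Spearman's rho was 0.960 for fold and 0.975 for width, and Pearson's r of log2 fold was 0.977. Peaks are not independent replicates, so no p is given. The ratio of fold between replicates had a median of 1.01, and its log2 had an SD of 0.33. No peak of the other replicate touched 3887 peaks (13.3%) of replicate 1 and 5625 (18.1%) of replicate 2, whose median folds were 3.03 and 2.93 against 20.2 and 19.6 for the touched peaks. The strongest peaks seen in replicate 1 alone lay near Rpl29 (chromosome 9, 106421663 to 106421998, fold 7.49) and in an intron of Col23a1 (chromosome 11, 51554700 to 51555133, fold 6.17). Others lay near Lmcd1 (chromosome 6, 112197499 to 112197997, fold 6.17), Irf2bp2 (chromosome 8, 126665791 to 126666140, fold 6.17) and in an intron of 2700089I24Rik (chromosome 19, 59541826 to 59542447, fold 5.95). In replicate 2 alone they lay near Rbm19 (chromosome 5, 120231962 to 120232308, fold 6.98), in introns of Arih1 (chromosome 9, 59483820 to 59484231, fold 6.53) and Firre (chromosome X, 50622944 to 50623354, fold 6.30). The remaining ones lay in an intron of Cept1 (chromosome 3, 106546146 to 106546485, fold 6.16), and in an exon of the globin gene Hbq1b (chromosome 11, 32286940 to 32287164, fold 5.85). Of the 32749 pooled peaks, 25277 (77.2%, Wilson 95% interval 76.7% to 77.6%) were kept as replicated. That interval treats peaks as independent trials, which they are not, and holds no spread between replicates. All 23500 pooled peaks that overlapped a peak of each replicate over 50% of the length of either were kept, and so were 1777 without such an overlap, which had a median fold of 3.04 against 27.2 for the others. With a reciprocal overlap of 80% the shares between replicates were 57.6% and 54.2%.

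**Figure D1:**
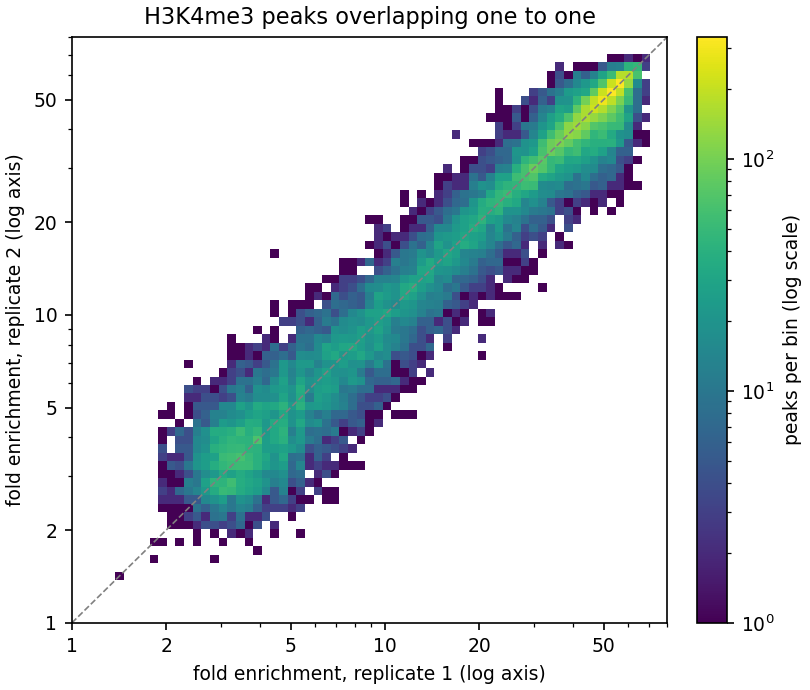
Fold over control in replicate 1 (x axis) against replicate 2 (y axis), both on log axes, with colour for the number of peaks per bin and the diagonal dashed, for the 20919 peaks that overlapped a single peak of the other replicate. The peaks lie along the diagonal with a Spearman's rho of 0.960.

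Promoters held most of the mark. Of the 25277 replicated peaks, 12 lay on unplaced or unlocalized scaffolds and were left out here. Of the others, 15946 (63.1%) had their centre within 1 kb of an annotated transcription start site (TSS). The centre lay in an exon for 1310 (5.19%), in an intron for 4027 (15.9%) and between genes for 3982 (15.8%). In the replicate lists the promoter share was 57.9% ± 1.40 (SD, n = 2), the exon share 5.80% ± 0.0987, the intron share 20.3% ± 1.09 and the share between genes 16.0% ± 0.209. Peaks shuffled within chromosomes fell near a TSS in 6.42% of cases (6.11% to 6.84% over 100 shuffles), so the observed share was 9.83 times the shuffled one. Exons held 1.52 times the shuffled share, introns 0.396 times and the space between genes 0.316 times. Each class lay outside all 100 shuffles, with a one-sided permutation p = 0.0099, the smallest that 100 shuffles can give. That p was taken in the direction each share showed and was not doubled for the choice of direction. The shares of the classes add up to a whole, so the high promoter share by itself lowers the intron and intergenic shares. The ratios and p of introns and of the space between genes are thus not separate results.

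Of 21938 protein-coding genes, 14736 (67.2%) had a replicated peak within 1 kb of a TSS, here called marked. The replicate lists marked 14759 and 14804 genes (14781.5 ± 31.8, SD, n = 2), and 14658 were marked in both. Long noncoding RNA genes were marked in 3122 of 13374 cases (23.3%), and in 1009 of 10536 (9.58%) when those within 2 kb of a coding TSS were left out. The genes of highest fold included Ipo7, a nuclear import receptor, with a fold of 75.6 (62.8 ± 4.11 in the replicates, SD, n = 2; chromosome 7, 110017972 to 110019940), Sfswap, a splicing regulator, with 75.4 (64.4 ± 2.00; chromosome 5, 129500192 to 129503006), and Ccnl2, a cyclin, with 74.99 (67.0 ± 0.874; chromosome 4, 155811725 to 155814527). Next came Clptm1 with 74.6 (61.6 ± 7.63), the shared promoter of Rnf166 and Ctu2 with 74.6 (58.2 ± 13.6; chromosome 8, 122474054 to 122477446) and Ssbp3 with 74.2 (66.6 ± 0.0638). The last were Pgs1 with 74.0 (66.0 ± 0.594), the proteasome subunit gene Psmb2 with 73.9 (64.2 ± 0.349) and Hnrnpul2, which shares its domain with Ttc9c, with 73.7 (66.8 ± 2.45). The domains of these genes spanned 1.58 to 7.59 kb, and the differences among their folds were no larger than the replicate SD of several of them.

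Genes of facial development were marked without exception when any annotated TSS counted, though not all were with the TSS at the 5′ end alone. All 36 transcription factor genes of cranial neural crest and facial mesenchyme carried the mark, in the replicated list and in each replicate, against 67.1% of other coding genes (two-sided Fisher's exact test, adjusted p = 4.84e-06 over 17 lists). So did all 31 facial signalling genes (adjusted exact p = 2.45e-05), among them Wnt5a, a ligand needed for outgrowth, the Hedgehog receptor gene Ptch1 and the Wnt effector gene Lef1. All 34 orofacial cleft genes (adjusted exact p = 1.15e-05) and all 22 housekeeping genes (adjusted p = 0.000742) were marked as well. Of the cleft genes, 16 also belong to another list. Markers of other cells present in the face divided. Epithelial genes were marked in 25 of 27 cases (Fisher's exact, adjusted p = 0.00636), including Pitx2, Esrp1 and Cldn6, while the desmosome gene Dsg3 and the cornification gene Ivl were not. Endothelial genes were marked in 19 of 20 (adjusted exact p = 0.0107), with Fli1, Esam and Ets1 the widest and Tie1 unmarked, with a peak in replicate 1 alone. Of the cartilage and bone genes 19 of 28 were marked (adjusted exact p = 1): Sox5, Sox6 and Pth1r were, and the late bone and hypertrophic cartilage genes Bglap, Bglap2 and Col10a1 were not.

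Marked less often than other genes were lists of blood, muscle, liver and germ cells. Pluripotency and germline genes were marked in 2 of 22 cases, Gdf9 and Dazl (4 of 22 in replicate 2), and not at Dppa2, Dppa3 or Ddx4, the last with a peak in replicate 2 (Fisher's exact, adjusted p = 3.86e-07). Gdf9 shares its domain with Uqcrq. Macrophage and leukocyte genes were marked in 3 of 21 (adjusted exact p = 4.84e-06), namely Ikzf1, Lcp1 and Fcgr3, with 5 of 21 in each replicate list, and not at Adgre1, Aif1 or C1qa. Liver and gut genes were marked in 7 of 24 (adjusted exact p = 0.000639), with Foxa1, Foxa3 and Cdx2 among them and with Afp, Alb and Apoa1, which encode abundant liver secretions, unmarked. Erythroid genes were marked in 6 of 20 (adjusted exact p = 0.00230), including Tal1, Epor and Klf1 but not Alas2, Ermap or Gata1. Skeletal muscle genes were marked in 9 of 23 (adjusted exact p = 0.0107): the progenitor gene Pax7 was, as were Mylpf and Tnnc1, whose domains are shared with Tbc1d10b and Nisch (Tnnc1 in replicate 1 alone), and Acta1, Actc1 and Chrna1 of contractile and synaptic muscle were not. The tests of 5 further lists did not pass: neurons and glia with 19 of 24 (Isl1, Tubb3 and Erbb3 marked, Neurod4, Dcx and Fabp7 not; adjusted exact p = 0.394), forebrain, eye and olfactory placode with 16 of 22 (Crx, Crybb2 and Crygd unmarked; 0.744) and Hox with 29 of 39 (0.518). The others were heart with 12 of 20 (Bmp10, Myh6 and Myl2 unmarked, adjusted exact p = 0.587) and the list of kidney, gonad, lung and thyroid. That list had 12 of 19 (Scgb1a1, Sftpb and Slc12a1 unmarked, adjusted exact p = 0.858). Within CpG-rich promoters, where 99.6% of other genes were marked, 6 calls of more frequent marking ended, 6 lists with a lower share than other genes turned direction (adjusted p = 1 in each, with 1 to 6 CpG-rich members per list), and Hox fell to 20.7 points under other genes, at 15 of 19 (Fisher's exact, adjusted p = 1.97e-05). The pluripotency and germline call held there, at 2 of 4 (Fisher's exact, adjusted p = 0.000965). The epithelial and endothelial calls ended when only the TSS at the gene's 5′ end was used (adjusted exact p = 0.108 and 0.103), and the muscle call ended with the pooled list (0.0640) and within promoters that are not CpG-rich (0.0665).

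**Figure D2:**
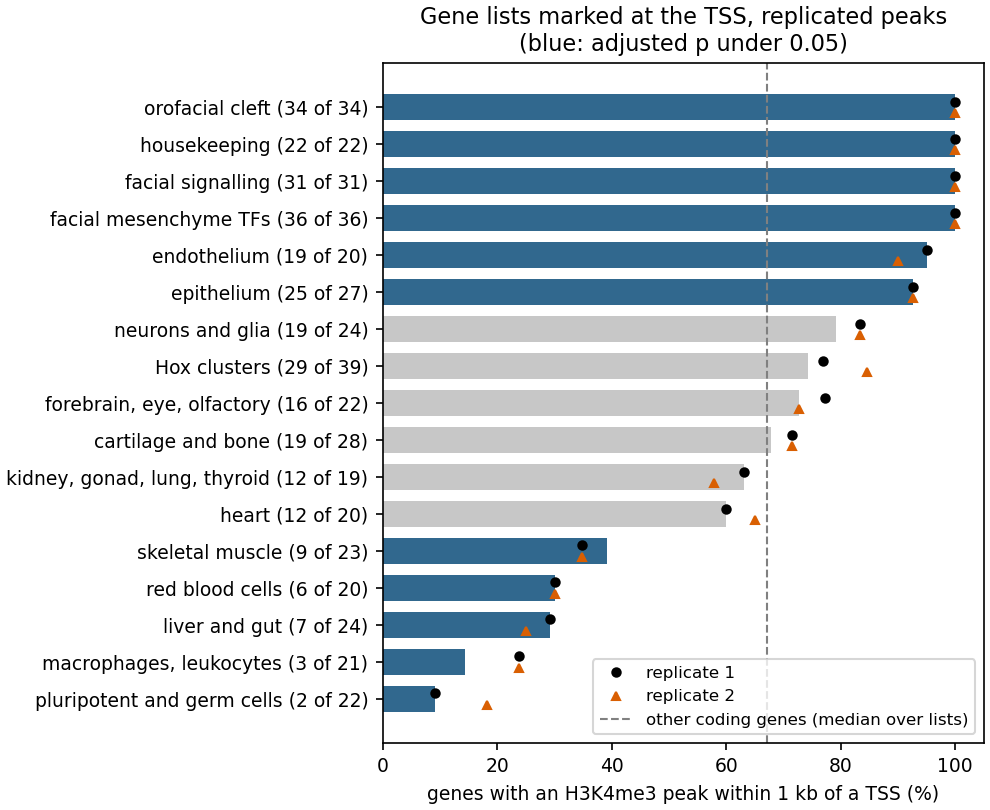
Percentage of each gene list marked by H3K4me3 within 1 kb of a TSS, in the replicated list (bars, blue where the adjusted p was under 0.05), in replicate 1 (circles) and in replicate 2 (triangles), with the share of other coding genes as a dashed line. The facial transcription factor, facial signalling, orofacial cleft and housekeeping lists stand at 100%, and the pluripotency and germline list at 9.09%.

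Among domains made by merging peaks within 1 kb, the widest was that of Tbx3, a T-box gene of outgrowing tissues, at 22.7 kb (19.7 ± 3.90 in the replicates, SD, n = 2; chromosome 5, 119665443 to 119688163). The POU gene Pou3f3 followed at 21.9 kb (21.8 ± 0.180; chromosome 1, 42684064 to 42706006) and the neural crest gene Pax3 at 18.9 kb (15.8 ± 2.22; chromosome 1, 78185665 to 78204610). Next were Alx1 at 18.5 kb (17.4 ± 2.49; chromosome 10, 103017721 to 103036247) and Satb2, a gene of palate and jaw development, at 18.1 kb (17.5 ± 0.517; chromosome 1, 56963198 to 56981322). Then came Ebf3 at 17.6 kb (18.6 ± 2.19), Trps1 at 17.4 kb (17.4 ± 0.107), the neural crest gene Tfap2a at 17.4 kb (17.1 ± 0.0580), Meis2 at 17.3 kb (17.1 ± 0.216) and Wnt5a at 17.0 kb (15.8 ± 1.13). None of these 10 domains holds the TSS of another coding gene. Each is wider than the widest single peak, of 16546 bp, and thus includes separate peaks. With touching peaks only the 10 widths ran from 4.91 to 15.2 kb, and 7 of them fell by over 1.5 times: Tbx3 to 12.3 kb, Pou3f3 to 12.2, Pax3 to 11.7, Alx1 to 6.56, Satb2 to 7.03, Trps1 to 4.91 and Tfap2a to 7.70. First place among these 10 changed with the merging. It went to Wnt5a with touching peaks only (15.2 kb) and to Tfap2a with merging within 3 kb (28.2 kb, against 27.4 at Tbx3). The folds of the strongest TSS peaks of these 10 genes were lower than those of the genes of highest fold, with 48.0 at Tbx3, 42.2 at Pou3f3 and 61.2 at Wnt5a. Marked coding genes had a median width of 2.35 kb and a median fold of 48.6. Across these genes, which are not independent replicates, the rank correlation of width and fold was 0.465.

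Taking as broad the widest 5% of coding TSS domains, those of at least 5.07 kb, 33 of 36 facial transcription factor genes (91.7%) were broad against 5.87% of other marked genes (two-sided Fisher's exact test, adjusted p = 4.30e-36). Their median width was 10.4 kb (9.77 ± 0.296 in the replicates, SD, n = 2), above the 1.97 to 2.81 kb that hold the central 95% of random lists of the same size. With touching peaks only their median was 7.45 kb, that of all marked genes 2.26 kb and the limit for broad 4.35 kb. Prrx2, Dlx4 and Tbx22, chosen after their values were seen, were the members under the limit, at 4.04, 3.79 and 0.850 kb. Facial signalling genes were broad in 20 of 31 cases (adjusted exact p = 1.48e-16; replicates 17 and 20), with Ptch1 at 15.8 kb (15.8 ± 0.559) and Lef1 at 12.02 kb (12.2 ± 0.283), and orofacial cleft genes in 16 of 34 (adjusted p = 1.36e-10). Of the 18 cleft genes in no other list, 7 were broad. Cartilage and bone genes were broad in 7 of the 19 marked (Fisher's exact, adjusted p = 0.000337), among them the chondrocyte regulators Sox6 at 11.3 kb (11.3 ± 0.0629; shared with 1110004F10Rik) and Sox5 at 8.81 kb (8.42 ± 0.469), and Pth1r at 8.81 kb (6.54 ± 2.17; shared with Myl3). Forebrain, eye and olfactory genes were broad in 5 of 16 (adjusted exact p = 0.00695). Six3, a forebrain and eye regulator, reached 14.3 kb (10.6 ± 5.15), Emx2 9.97 kb (9.86 ± 0.442) and Ebf2 7.64 kb (7.52 ± 0.00354), with folds of 20.3, 28.0 and 16.8. Housekeeping genes were broad in 5 of 22 (adjusted exact p = 0.0258; replicates 4 and 3), with Rpl13a at 9.05 kb (shared with Rps11), Actb at 5.49 kb and Tbp at 5.37 kb (shared with Psmb1). Their median width was 3.68 kb and their median fold 62.2. With touching peaks only, Ptch1 had 8.92 kb, Lef1 5.78, Sox5 4.05, Pth1r 5.34 and Six3 7.25, and with merging within 3 kb Emx2 had 20.7 kb.

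Markers of the remaining cell types did not pass the test for broad domains, against 6.06% of other marked genes in the heart and epithelial tests. Heart genes were broad in 3 of 12 cases (Myl3, Hand1 and Irx4; 1 in replicate 1 and 3 in replicate 2; two-sided Fisher's exact test, adjusted p = 0.0792), and in 1 of 12 with touching peaks only. Epithelial genes were broad in 4 of 25 (4 in replicate 1 and 2 in replicate 2; Pitx2 8.86 kb, Esrp1 5.70 kb and Cldn6 5.25 kb, shared with Cldn9, among them; adjusted exact p = 0.132). Single broad members stood in the muscle list (1 of 9, Pax7 at 7.90 kb; adjusted exact p = 0.734), the endothelial list (1 of 19, Fli1 at 7.001 kb; p = 1) and the neuronal list (1 of 19, Isl1 at 7.17 kb; p = 1). The erythroid (0 of 6), macrophage (0 of 3), liver (0 of 7, but 1 in replicate 1), kidney (0 of 12) and pluripotency (0 of 2) lists had none (Fisher's exact, adjusted p = 1 in each), where Tal1 reached 4.34 kb, Ikzf1 2.04 kb, Foxa1 4.84 kb, Amh 4.59 kb (marked in replicate 1 alone) and Gdf9 2.16 kb. Hnf1b at 3.89 kb, Sftpc at 4.08 kb (shared with Bmp1), Foxa3 at 2.97 kb (shared with Sympk) and Cdx2 at 2.89 kb (0.711 ± 0.170 in the replicates, SD, n = 2) were likewise under the limit. With touching peaks only Cldn6 had 2.63 kb, Isl1 3.25, Tal1 2.28, Foxa1 2.25, Hnf1b 0.846 and Cdx2 0.944, and with merging within 3 kb Pitx2 had 14.3 kb, Cldn6 11.5, Pax7 15.7, Isl1 11.5, Tal1 7.84 and Foxa1 8.69. The housekeeping call ended in the list of either replicate alone (adjusted exact p = 0.368 and 0.117), with touching peaks only (0.814), with merging within 3 kb (0.391), among the strictly matched peaks (0.0980) and among peaks with a −log10 q of at least 5 (0.0951), and 0.119 was its adjusted p without domains that hold another coding TSS. The forebrain call ended with touching peaks only (0.196) and with the widest 10% (0.0830). The epithelial list passed with these 2 settings (exact p = 0.0110 and 0.0193), among the strictly matched peaks (0.0433) and with a −log10 q of at least 5 (0.0417), and the heart list with merging within 3 kb (0.000336). The epithelial share was only 0.924 points over other genes with merging within 3 kb (adjusted exact p = 0.874) and 1.66 points with the pooled list.

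**Figure D3:**
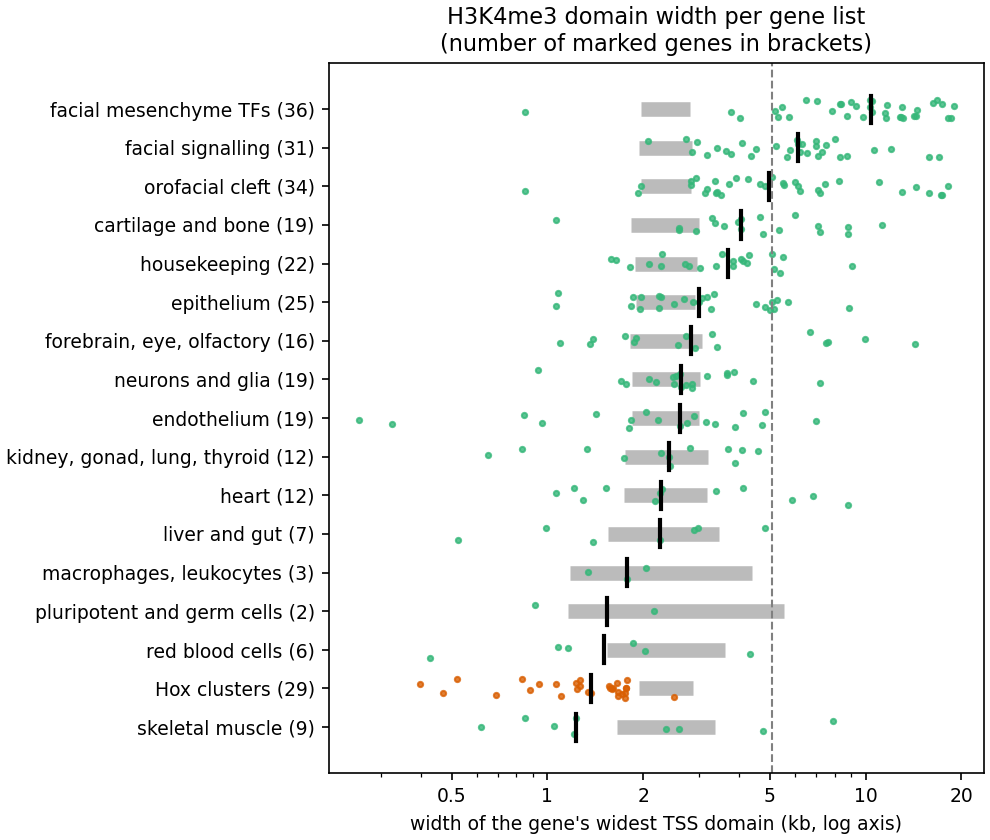
Width in kb of the H3K4me3 domain at the TSS of each marked gene (points, log axis) in each fixed list, with the list median (black), the central 95% of medians of random lists (grey) and the limit of 5.07 kb for broad domains (dashed). The facial transcription factor genes have a median of 10.4 kb and the Hox genes a median of 1.37 kb.

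Most marked Hox genes carried weak and narrow marks. Hox genes encode axial position and, by prior knowledge, are not expressed in the cranial neural crest of the face. Expression was not measured here. The 29 marked genes had a median fold of 5.27 (5.55 ± 0.0564 in the replicates, SD, n = 2) and a median width of 1.37 kb (1.28 ± 0.0223). Both were below each of 10000 random lists of 29 marked genes, whose central 95% ran from 39.4 to 55.4 for fold and from 1.94 to 2.88 kb for width. Low fold was not particular to Hox genes. Median folds of the endothelial (18.4), neuronal (19.0), heart (12.6) and kidney (11.1) lists also stood at percentile 0 of their random lists. Skeletal muscle had a median fold of 8.71 and a narrower median width, of 1.23 kb. The facial transcription factor, signalling and cleft lists lay within the central 95% for fold. None of the 29 was broad (two-sided Fisher's exact test, adjusted p = 0.734). The strongest were Hoxa1 with a fold of 33.8 (28.1 ± 2.61), Hoxa7 with 29.4 (23.8 ± 6.50), Hoxd1 with 28.2 (24.9 ± 3.95), Hoxd8 with 21.9 (19.7 ± 0.771), which was also the widest at 2.496 kb, Hoxa4 with 21.03, Hoxc6 with 19.0 and Hoxa13 with 16.3 (14.4 ± 3.83). Hoxd13 had 10.9, Hoxd9 10.6, Hoxd3 and Hoxd4 on a shared domain 9.75, and Hoxc13 8.23. The remaining 17 marked genes had folds from 2.73 at Hoxb7 (replicate 1 alone) to 5.81 at Hoxd11, with Hoxb8 at 2.79, Hoxa2 (replicate 2 alone) at 3.02, Hoxd10 at 3.03 and Hoxb13 at 5.27. Hoxa6 and Hoxa11 were unmarked in the replicated list but had weak peaks in both replicates (2.93 ± 0.952 and 2.84 ± 0.0306), and Hoxa9 had one in replicate 2.

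By cluster, 8 of 11 Hoxa genes were marked (chromosome 6, 52150590 to 52265880), 6 of 10 Hoxb genes (chromosome 11, 96189316 to 96373256), 7 of 9 Hoxc genes (chromosome 15, 102916103 to 103041852) and 8 of 9 Hoxd genes (chromosome 2, 74663310 to 74770142). Peaks covered 11.9% of the Hoxa cluster, 4.97% of Hoxb, 7.19% of Hoxc and 16.9% of Hoxd, and the highest fold within each was 33.8, 5.83, 19.0 and 28.2. Genes of the anterior paralog groups 1 to 4 were marked in 9 of 12 cases (75%) and those of the posterior groups 9 to 13 in 11 of 16 (68.75%), a difference that did not pass the test (two-sided Fisher's exact p = 1). Groups 5 to 8, outside that test, were marked in 9 of 11. The direction of the difference turned in each replicate list, with 8 of 12 against 12 of 16 in replicate 1 and 10 of 12 against 14 of 16 in replicate 2. The number of marked Hox genes was 30 and 33 in the replicates, and the test of the Hox share passed with the pooled list (adjusted exact p = 0.00494) and with replicate 2 alone (0.0385).

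**Figure D4:**
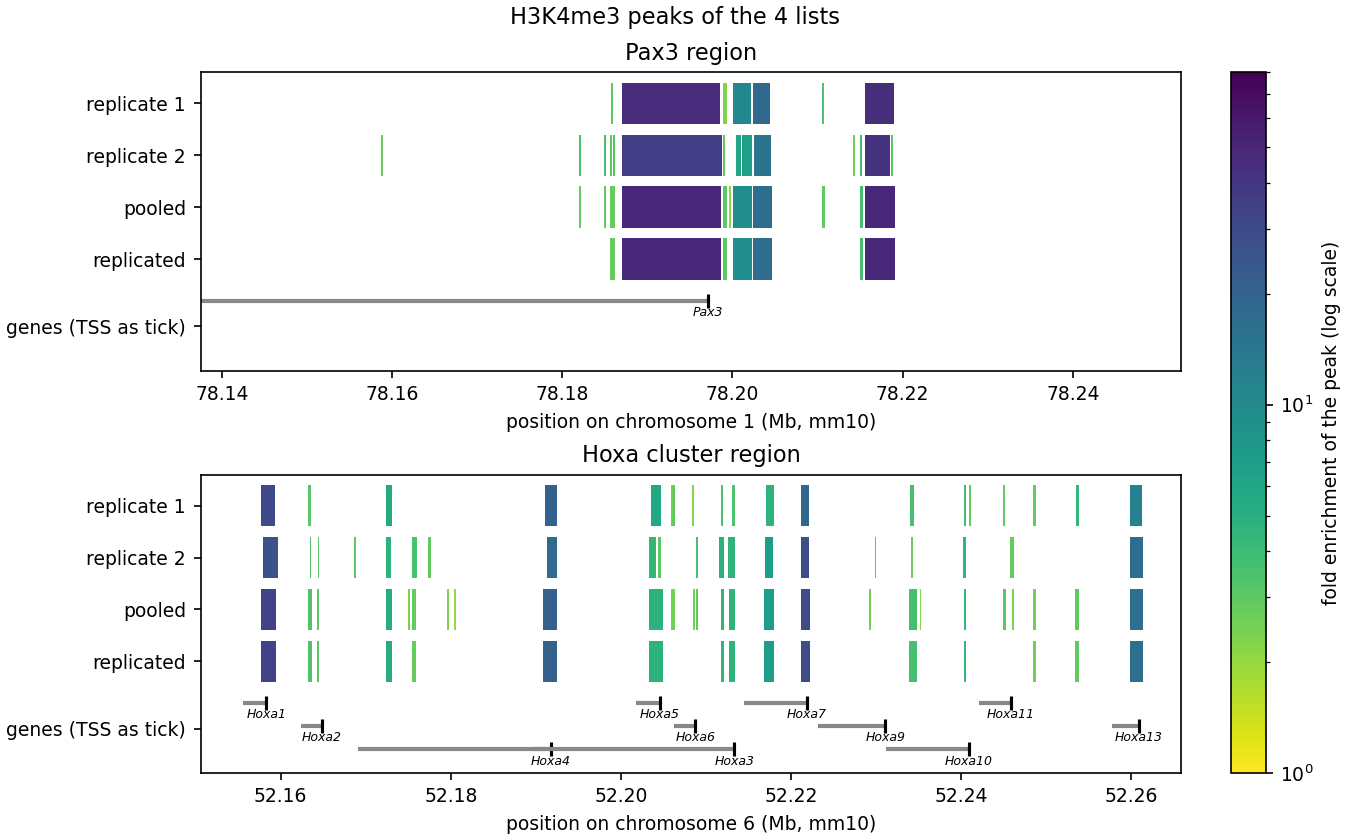
H3K4me3 peaks of the 4 lists, coloured by fold over control on a log scale, along 2 regions of equal length on genome build mm10 (x axes, Mb), around Pax3 on chromosome 1 and across the Hoxa cluster on chromosome 6, with Pax3 and the Hox genes drawn to scale and each TSS as a tick. The merged Pax3 domain spans 18.9 kb, of which a single peak of 11.7 kb has the fold of 49.0, and the highest fold in the Hoxa cluster is 33.8.

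Promoter CpG content separated marked from unmarked genes. CpG-rich promoters were marked in 6503 of 6532 cases (99.6%) and others in 8233 of 15406 (53.4%), with an odds ratio of 195 (Wald 95% interval 135 to 282). The two-sided Fisher's exact p lay under 2.23e-308, the smallest normal floating-point number. The replicate lists gave 99.5% and 99.6% for CpG-rich promoters and 53.6% and 53.9% for others. The median CpG observed over expected was 0.6004 at marked genes (interquartile range 0.462 to 0.717) and 0.162 at unmarked ones (0.111 to 0.233), and median GC was 53.9% and 43.8%. Among promoters that are not CpG-rich, a split added after the data were seen, all 17 facial transcription factor genes (Fisher's exact, adjusted p = 0.000146), all 12 facial signalling genes (0.00156) and 15 of 16 endothelial genes (0.00160) were marked, while 1 of 19 macrophage genes (0.000146), 1 of 18 liver genes (0.000150) and 0 of 18 pluripotency genes (1.78e-05) were.

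Away from promoters the mark was weaker and narrower. Over 5 kb from any TSS lay 5163 replicated peaks (20.4%; 20.5% ± 0.281 in the replicates, SD, n = 2), 2131 of them inside genes and 3032 between genes. Their median width was 637 bp (interquartile range 431 to 947) and their median fold 5.11 (3.55 to 9.99), against 1969 bp and 42.3 (19.5 to 55.4) for the 15946 peaks within 1 kb of a TSS. Both replicates had a peak at 86.5% of the distal and 97.6% of the promoter peaks. The replicated list was itself kept by comparison with the replicates, so these shares are high by selection and measure no independent agreement. The distal peaks of highest fold lay 5.72 kb from Zfp869 (chromosome 8, 69715222 to 69717658, fold 60.3; 53.3 and 54.7 in the replicates) and in an intron of Lncppara 62.9 kb from Ppara (chromosome 15, 85669424 to 85674670, 60.2; 51.4 and 54.9). Others lay in introns of Macrod1 (chromosome 19, 7164102 to 7166735, 58.8; 54.6 and 50.6) and Tns3 (chromosome 11, 8620965 to 8625296, 57.5; 51.3 and 51.5), and 19.4 kb from Fcgr4 (chromosome 1, 171037649 to 171038997, 56.6; 48.2 and 44.7). The widest distal domains lay between genes, with 9.18 kb near Olfr1423 (chromosome 19, 12004583 to 12013766), 7.86 kb near Trim27 (chromosome 13, 21166289 to 21174145), 7.10 kb near Hfe2 (chromosome 3, 96496550 to 96503653), 6.94 kb near Cbx8 (chromosome 11, 119052365 to 119059308) and 6.75 kb near Dhx37 (chromosome 5, 125403577 to 125410329). Nearest genes are given for position alone, and no link between these peaks and those genes was tested.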

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

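Chosen only after the results were seen were the tests of shared domains, of cells from neighbouring tissue at Hox genes, of kept peaks near the calling limit and of signal from a single library. The merging setting was among the alternatives fixed before the data were examined. The comparisons with CpG-matched lists, for facial and for Hox genes, were not among those alternatives, though their expected outcomes were written before they were run. The samples form 1 group, so no biological explanation was tested for any pattern.

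Peaks outside the main measurement held signal in 2 places. On unplaced or unlocalized scaffolds lay 12 replicated peaks, with folds from 2.20 to 38.3, of which 11 had peaks in both replicates and 1, of fold 2.20, in replicate 2 alone. The pooled list marked 171 coding genes that the replicated list does not, with a median fold of 2.58 and a highest fold of 4.81 at Hbq1b, named here after its value was seen.

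The 36 facial mesenchyme transcription factor genes had a median domain of 10.4 kb and 33 of them were broad. With touching peaks only 91.6667% of the marked members were broad (33 genes, Fisher's exact, adjusted p = 4.15e-36). Among the 35 members with no other coding TSS in their domain 91.4286% were (32 genes, Fisher's exact, adjusted p = 7.53e-38). Neither merging nor neighbouring coding genes thus accounts for the share of broad members, and noncoding TSSs in the domains were not counted. Merging does add to the widths, since the median with touching peaks only was 7.45 kb. Lists matched on the number of CpG within 5 kb of the TSS had a median width of 3.68 kb (central 95% 3.08 to 4.47 kb), and the observed median stood at percentile 100 of them. The CpG number thus does not account for the median width alone, though the matched median was above the 2.35 kb of all marked genes. The share of broad members was not computed in the matched lists. The list was compared with all other marked genes, not with other transcription factor genes. Among families chosen after the data were seen, with no member on the list, 5 of 6 Irx, 3 of 4 Ebf and 3 of 4 Nfi genes were broad. Of the marked Pou genes 1 of 11 and of the marked Zfp genes 18 of 350 were. Broad domains were thus not particular to this list. A hypothesis is that broad domains may go with the regulatory state of these genes in this tissue. No second tissue is at hand here as a test of it.

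The 29 marked Hox genes had a median fold of 5.27 and a median width of 1.37 kb. Lists of marked genes with as many CpG near the TSS had a median fold of 52.4 (44.1 to 58.1) and a median width of 3.28 kb (2.79 to 3.98 kb), with the Hox fold at percentile 0, which argues against low CpG content. Cells of neighbouring Hox-expressing tissue in the dissected sample cannot be told apart from a weak mark in the facial cells themselves, since the files hold no such tissue. Among marked genes the median fold was 9.75 in the 9 of groups 1 to 4 against 5.27 in the 11 of groups 9 to 13 (exact permutation p = 0.335), too few genes to decide. Hoxd3 and Hoxd4 share 1 domain and the fold of 9.75, which is that median, and the test counts them as 2 genes. A weak mark on silent, poised genes is a candidate explanation that no file here can test.

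The 1777 replicated peaks without a 50% overlap in both replicates had a median fold of 3.04 and a highest fold of 5.32, against a 25th percentile of 6.71 in the other kept peaks. Peaks near the calling limit and signal of a single library stay open and cannot be told apart: the median of 3.04 decides nothing, since no pooled peak without a match in both replicates exceeded a fold of 5.32. Of the 1777 peaks 43 (2.42%) touched a peak of each replicate, 698 one of replicate 1 alone, 923 one of replicate 2 alone and 113 neither, and leaving out matched peaks fixes that share, because 99.6% of all pooled peaks that touch a peak of each replicate also match both. A share of 21.4% lay within 1 kb of a TSS against 66.3% of the other kept peaks. Depth per library is unknown, so the calling limit itself could not be measured.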

How the results depend on the processing

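Chosen only after the results were seen were the strict list, the genes with no other coding TSS within 2 kb, the genes with no other coding TSS in the domain and the promoters that are not CpG-rich. List values are percentage points, list minus other genes, with Benjamini-Hochberg adjusted p of two-sided Fisher's exact tests in brackets, and except where stated the cause was not tested. The facial transcription factor list kept its direction and call for broad domains under all its alternatives (79.9 to 87.6), and 17 of 17 lists kept theirs for marking with TSS windows of 500 bp and 2.5 kb, with the strict list and without neighbouring TSSs. Marked coding genes numbered 13957 to 14935 over the alternatives (14736 in the reported list). Of 89 named marked genes, 85 to 89 stayed marked under each setting, and of 36 named unmarked genes 6 became marked with the pooled list, 5 without replicate 1, 4 without replicate 2, 4 with a 2.5 kb window and 0 under the other settings. Among these 89, 31 domains became narrower by over 1.5 times with touching peaks only and 15 wider with merging within 3 kb. The CpG difference was 46.1 points and 46.4 to 58.1 over its alternatives. Depth is unknown, so what it limits cannot be stated.

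Overlap between replicates (82.3% and 77.0%) was 86.7% and 81.9% with 1 bp, 57.6% and 54.2% with 80% both ways, as a looser or stricter limit gives by construction, and 95.3% and 95.5% among the strongest 20000 peaks. With a −log10 q of at least 5 the overlap was 93.3% and 92.8%, rho of fold 0.946 (0.960), kept peaks 97.4% (77.2%), promoter peaks 65.9% (63.1%) and distal peaks 19.4% (20.4%). At that limit Hox marking was −0.240 (exact p = 1; 7.20 in the reported list), broad epithelium 14.0 (0.0417), broad housekeeping 12.2 (0.0951) and Hox groups 1 to 4 minus 9 to 13 −2.08 (1; 6.25 in the reported list). The strict list gave kept peaks 71.8%, promoter 66.3%, distal 19.0%, broad epithelium 14.0 (0.0433), broad housekeeping 12.2 (0.0980) and Hox groups −2.08. The promoter share was 51.9% with a 500 bp and 72.8% with a 2.5 kb window, and the distal share 27.2% over 2.5 kb and 14.0% over 10 kb, by construction.

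Leaving out each replicate in turn gave a promoter share of 56.9% to 58.9%, Hox marking of 9.66 to 17.2 (0.306 without replicate 2, 0.0385 without replicate 1), broad housekeeping of 7.47 to 12.1 (0.368 and 0.117), broad heart of 2.25 (0.818, without replicate 2) to 16.9 (0.120), broad epithelium of 1.82 (1, without replicate 1) to 9.93 (0.151), broad liver and gut of −6.18 to 8.21 (0.671 at the higher) and Hox groups of −8.33 to −4.17 (0.691 and 1). With the TSS at the 5′ end alone, marking was 17.9 (0.108) for epithelium and 21.4 (0.103) for endothelium (25.5 and 27.9 in the reported list). The pooled list gave marking of −20.1 (0.0640) for muscle and 21.8 (0.00494) for Hox, broad endothelium 3.66 (0.690) and Hox groups −10.4 (0.560).

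Among CpG-rich promoters 99.6% of other genes were marked, which leaves no room for a list to exceed them. There marking was 0.445 for facial transcription factors, signalling, cleft, epithelium and housekeeping and 0.444 for endothelium (exact p = 1 each, calls ended), and 0.444 for muscle, erythroid, macrophage, liver, heart and kidney (p = 1 each, direction turned from −28.1, −37.2, −52.9, −38.0, −7.18 and −4.02), while Hox was −20.7 (1.97e-05) and pluripotency and germline −49.6 (0.000965), whose call held. Among promoters that are not CpG-rich, 16 of 17 lists kept direction and call, and muscle was −23.5 (0.0665).

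For broad domains, touching peaks only gave epithelium 18.0 (0.0110; 9.94 in the reported list), forebrain 12.7 (0.196; 25.2) and housekeeping 3.02 (0.814; 16.7). Merging within 3 kb gave erythroid 9.59 (0.606), neurons 8.72 (0.358), liver 7.21 (0.621), heart 43.0 (0.000336; 18.9), kidney 9.60 (0.391) and housekeeping 6.57 (0.391). The widest 10% gave epithelium 20.1 (0.0193), endothelium 9.11 (0.453), erythroid 4.72 (0.757), forebrain 19.3 (0.0830), liver 2.34 (0.771) and kidney 4.72 (0.785). Without domains that hold another coding TSS, endothelium was 0.597 (0.904), neurons 1.29 (0.904) and housekeeping 13.8 (0.119).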

Other observations

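The 18 gene families here were chosen only after the data were seen, with a two-sided Fisher's exact test per family and Benjamini-Hochberg adjustment over the families, and family members share ancestry and in places a cluster, so they are not independent.

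Several families of developmental regulators, whose members in part belong to the fixed lists, were rich in broad domains. Of the Iroquois genes 5 of 6 were broad (Irx1 to Irx5; adjusted exact p = 6.37e-05), with a median width of 7.01 kb. Of the marked Sox genes 8 of 19 were broad (Sox2, Sox4, Sox5, Sox6, Sox9, Sox11, Sox12 and Sox21; adjusted exact p = 6.37e-05), 4 of 6 of the family of Six1, Six2, Six3 and Six5 (0.00105), of the Tbx genes 5 of 11 (Tbx1, Tbx2, Tbx3, Tbx15 and Tbx18; 0.00119), of the Fox genes 9 of 38 (0.00122), of the Ebf genes 3 of 4 (Ebf1, Ebf2 and Ebf3; 0.00208), of the Nfi genes 3 of 4 (Nfia, Nfib and Nfix; 0.00208), of the Bmp genes 3 of 7 (Bmp2, Bmp4 and Bmp7; 0.0138) and of the Lhx genes 3 of 8 (Lhx2, Lhx6 and Lhx8; 0.0188). The Wnt genes (3 of 19; 0.162), Fgf genes (3 of 19; 0.162), Pou genes (1 of 11; 0.652), ribosomal protein genes (8 of 88; 0.363), Zfp genes (18 of 350; 0.693) and clustered protocadherins (1 of 33; 0.817) did not pass.

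Large families of sensory and hair genes were almost unmarked. Olfactory receptor genes were marked in 3 of 1135 cases (0.264%) in the replicated list and in each replicate (p under 2.23e-308, the smallest normal floating-point number), vomeronasal receptor genes in 1 of 331 (adjusted exact p = 2.68e-159) and keratin-associated protein genes in 0 of 57 (1.38e-27). Zfp genes were marked in 350 of 394 cases against 66.8% of other genes (4.94e-23) and ribosomal protein genes in 88 of 98 (8.18e-07). The clustered protocadherin genes were marked in 33 of 57 cases (0.257; 31 and 35 in the replicates), with a median width of 0.715 kb and a median fold of 5.07.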
